A study of Hydra viridissima with 2 samples.

How the data were processed

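Whole polyps of the green hydra Hydra viridissima, clone 2, were profiled by paired-end sequencing of total RNA after enzymatic removal of ribosomal RNA, per the labels' protocols. There was 1 library from polyps without their algae (aposymbiotic) and 1 from green, alga-bearing polyps (symbiotic). The molecule field of the labels says polyA RNA, whereas the protocol text describes total RNA; the protocol text was followed here. The submitters' processing notes name fastp 1.1.0, STAR 2.7.11b and deepTools 3.5.6, and per the file headers the counting started from coordinate-sorted alignments and a STAR index.

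The deposited table holds counts per gene model, made by the authors with featureCounts of Subread 2.1.1, per the file headers. Per the file headers, read pairs were counted over exons and summed per gene, with no strand setting and no option that admits reads with several alignments or reads that overlap several models. Sense and antisense transcripts can therefore not be told apart, and 322 of the 34573 models overlap a model on the opposite strand. The annotation was a BRAKER3 set called conservative, per the file headers; the genome build is not given in the sources used here. Coordinates are those of the table. Exon lengths are multiples of 3 in 98.4% of models, so lengths are called coding lengths. The files do not pair the identifiers with gene names and no reference genome was used, so genes are given by position and at most 2 identifiers per direction are printed. The lists of nematocyte, neuron, gland cell, stem cell, cell cycle, epithelial and algal genes that were fixed before the data were examined could not be formed, and 0 of them were analysed.

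From the deposited counts, CPM, the counts scaled to a common library total, were computed on library sizes scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. The factors were 1.01 for the aposymbiotic and 0.991 for the symbiotic library. The log2 ratio of symbiotic over aposymbiotic CPM was taken with a prior count of 0.5 scaled to library size. Each ratio has an exact 95% interval (Clopper-Pearson, conditional on the sum of both counts). With 1 library per condition there was no test, no p-value and no replicate check, and intervals and floors cover counting error only. Each difference is one between these 2 libraries. Genes entered with a mean CPM of at least 1, which 16162 models met. A gene was counted as higher or lower when its ratio was at least 2-fold (or, under a stricter rule, 4-fold) and its interval excluded equality. To see what counting error gives by itself, 100 pairs of libraries were drawn from Poisson distributions with the pooled proportions and the real totals.

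The rule for named genes, fixed before the data were examined, ranked genes of a mean CPM of at least 5 by the interval bound nearest to equality and took the first 2 identifiers in each direction. Other loci are given by coordinates and were chosen after their values were seen. Where 1 library had 0 counts, the fold is a lower bound against a floor of 3 counts in that library. It takes the other library's count as measured, so the lower end of the counting interval, which covers the error of both counts, lies below it. Medians by gene structure have exact order-statistic 95% intervals over genes, which are not replicates. Simulated counts for this comparison, with 16013 genes tested, checked the procedure: 87% of genes set to differ 3-fold and 95% of those set to differ 8-fold met the 2-fold rule, 0 of them in the wrong direction. Of all counting intervals, 94.1% held the simulated ratio. A simulated difference of 0.14 in log2 ratio between the longest and the shortest length class came back as 0.17. The simulated counts had Poisson error only, so they check the calculation and not whether the intervals are wide enough for these libraries. In the real data, the robust standard deviation of the log2 ratio was 1.11 times that of counting error among genes of 20 to 50 counts. It was 3.80 times among genes of 3000 or more counts, and the intervals do not cover this excess.

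Alternatives were other scalings (total counts alone, RLE, upper quartile, totals without the 100 largest genes), other count filters, no interval or a stricter one, a prior count of 5, and other minimum counts for genes seen in 1 library. Leaving out scaffold 60 was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.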

Results

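Green hydra is a small freshwater polyp that carries green algae inside the epithelial cells lining its gut, and aposymbiotic polyps are animals without them. The comparison asked how transcript levels of whole polyps differ with and without the alga. The aposymbiotic library held 5533508 read pairs counted on gene models and the symbiotic library 6905650. Of 34573 gene models on 105 scaffolds, 14546 had at least 10 counts in the aposymbiotic and 15127 in the symbiotic library. The 20 largest genes took 10.6% of the aposymbiotic total (95% Clopper-Pearson interval 10.6 to 10.7) and 11.3% of the symbiotic total (11.2 to 11.3), and 18 genes were among the 20 largest in both libraries.

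The clearest difference lay on scaffold 60, a short scaffold whose 15 gene models had 1009 counts in the symbiotic library and 0 in the aposymbiotic library. On scaffold 6, a neighbouring pair of models was 5.70-fold and 9.63-fold higher in the aposymbiotic library. A 9-exon gene on scaffold 12, with a mean of 2860 CPM, was 3.14-fold higher in the aposymbiotic library. Most other genes had similar levels with and without the alga. Pearson's r of log2(CPM + 1) was 0.986 and Spearman's rho 0.983 across the 16162 genes with a mean CPM of at least 1, where genes are not independent replicates. Of the 9483 genes with a mean CPM of at least 10, 94.7% lay within 0.5 of equality on the log2 scale.

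By the 2-fold rule, 153 genes were higher and 229 lower in the symbiotic library, 0.947% and 1.42% of those tested. Counting error alone gave on average 64.1 genes at least 2-fold higher (49 to 87 over 100 draws) and 67.7 lower (52 to 88), so part of the calls among low-count genes is within what counting error gives. By the 4-fold rule, 45 were higher and 49 lower, where counting error gave on average 11.7 (5 to 19) and 8.13 (1 to 16). These fell to 5 and 6 genes at a mean CPM of at least 10, and to 20 and 15 with a prior count of 5. Among genes with a mean CPM of at least 10, 13 were higher and 51 lower, where counting error gave at most 2 and 1. Scaffold 60 contributed 11 of the 153 higher genes, and 2 of those 13. Among the 1992 genes with a mean CPM of at least 100, 0 were at least 2-fold higher and 10 were at least 2-fold lower in the symbiotic library. Most genes past the 2-fold rule were of low expression, with a median of 2.58 CPM among the higher and 2.95 among the lower genes, against 16.1 among tested genes that met neither rule.

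**Figure D1:**
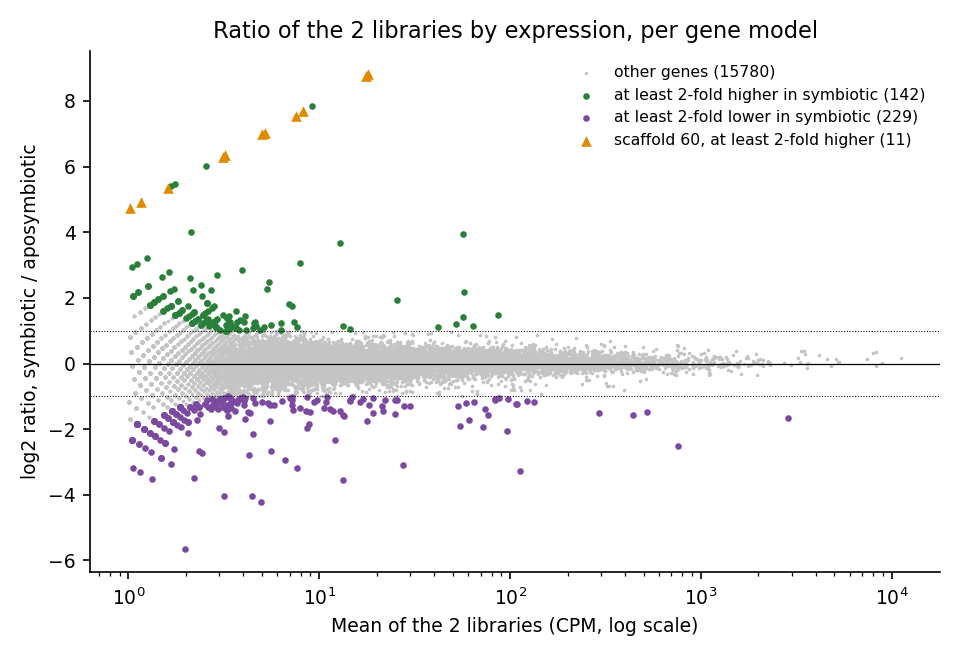
Log2 ratio of symbiotic over aposymbiotic CPM (vertical axis, prior count 0.5) against the mean CPM of the 2 libraries (horizontal log axis), 1 point per gene model with a mean CPM of at least 1. Dotted lines mark 2-fold; the 11 tested models of scaffold 60 (triangles) had 0 aposymbiotic counts, so their height depends on the prior count, and the 10 genes past 2-fold with a mean CPM of at least 100 are all lower in the symbiotic library.

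Scaffold 60 carried models between positions 1766 and 57115, and 13 of the 15 had a single exon. Each of the 15 had counts in the symbiotic library, from 6 to 246, and none had a count in the aposymbiotic library. Summed over the scaffold, the symbiotic level was at least 275-fold higher, against a floor of 3 aposymbiotic counts for the whole scaffold, and the lower end of the 95% counting interval was 223-fold. These counts were 0.0146% of the symbiotic total (95% Clopper-Pearson interval 0.0137 to 0.0155), and the floor is 5.42e-05% of the aposymbiotic total. The first genes by the ranking were on this scaffold. Model cHydvir-v1B3C1_g28448 (scaffold 60, positions 35875 to 36261, minus strand, 1 exon, 387 nt) had 246 symbiotic counts and was at least 67.0-fold higher against the floor, with the lower end of its 95% counting interval at 54.1-fold. Model cHydvir-v1B3C1_g28451 (positions 48836 to 50401, minus strand, 1 exon, 1566 nt) had 240 symbiotic counts and was at least 65.3-fold higher against the floor, with the lower end at 52.7-fold. Together they held 48.2% of the scaffold's counts. Models at the left end, from 1766 to 3841 and from 4139 to 5617, had 113 and 103 symbiotic counts. A pair at the right end, from 54639 to 55415 and from 56327 to 57115, had 69 and 71. Counts per kilobase of coding length ranged from 9.20 to 636 across the 15 models. None of the 15 overlaps another model. Over the 16 scaffolds with most models, which hold 94.6% of models, the log2 ratio of the summed counts ran from -0.02 to 0.07. Each of these sums runs over at least 979 models. Small scaffolds with few counts varied more, such as -0.79 on scaffold 51 (37 aposymbiotic and 26 symbiotic counts) and 1.15 on scaffold 145 (6 and 17). Scaffold 60 was the only 1 with at least 20 counts in 1 library and 0 in the other.

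**Figure D2:**
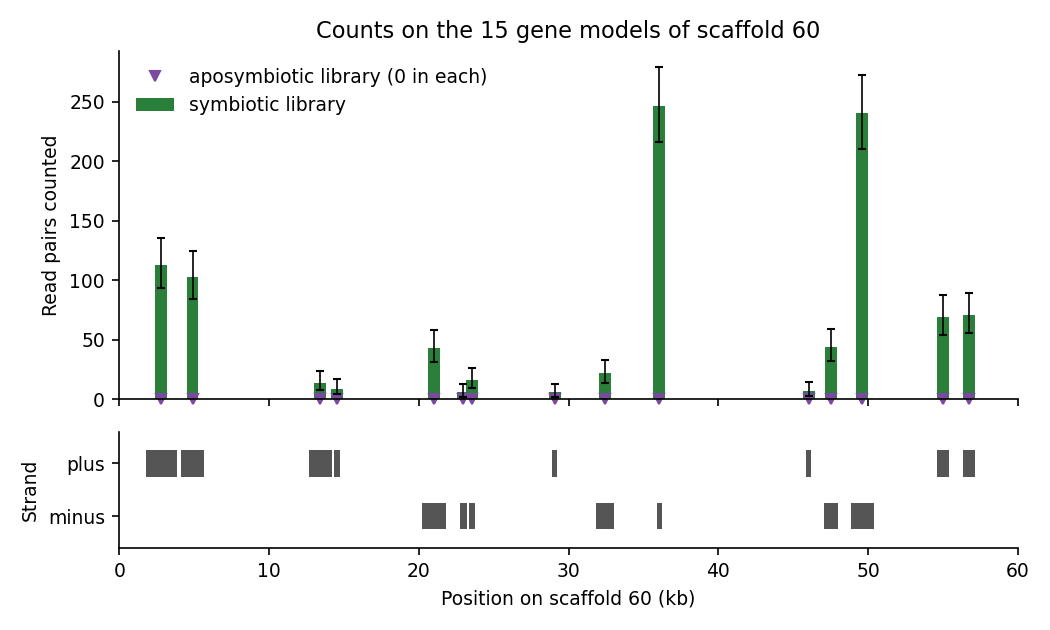
Read pairs counted per gene model along scaffold 60 (upper panel, bars for the symbiotic library with exact 95% Poisson intervals, triangles for the aposymbiotic library) and the extent and strand of each model (lower panel, positions in kb). All 15 models had 0 aposymbiotic counts, and symbiotic counts ranged from 6 to 246.

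Away from scaffold 60, 4 other models had at least 20 symbiotic counts and 0 aposymbiotic counts, where 100 draws of counting error alone gave 0 such genes. A single-exon model on scaffold 7 (6765822 to 6766556, minus strand, 735 nt) had 126 symbiotic counts and was at least 34.3-fold higher. A 3-exon model on scaffold 7 (6168427 to 6170623) had 35 symbiotic counts and was at least 9.53-fold higher. A 13-exon model on scaffold 3 (15336725 to 15348355) had 24 and was at least 6.53-fold higher. On scaffold 2, a 2-exon model (20420292 to 20421053) had 23 and was at least 6.26-fold higher. In the other direction, a 2-exon model near the start of scaffold 1 (40222 to 41176) had 22 aposymbiotic and 0 symbiotic counts, at least 8.98-fold higher in the aposymbiotic library. At 20 counts or more, 13 models were thus seen in the symbiotic library alone, 9 of them on scaffold 60, and 1 in the aposymbiotic library alone.

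Among genes with counts in both libraries, the first higher gene by the same ranking was a 5-exon gene on scaffold 8 (13842505 to 13844047, minus strand). It had 6.80 CPM in the aposymbiotic and 106 CPM in the symbiotic library, 15.6-fold higher (95% counting interval 11.3 to 22.3). A 7-exon gene on scaffold 6 (14968064 to 14971520) had 10 and 164 counts, 13.4-fold higher (7.10 to 28.5). A single-exon gene on scaffold 13 (1608261 to 1608950) had 9 and 97 counts, 8.80-fold higher (4.45 to 19.8). A 6-exon gene on scaffold 12 (2003720 to 2005807) was 4.55-fold higher (3.73 to 5.59), at 20.8 and 94.4 CPM. The 10-exon gene on scaffold 4 at 1393283 to 1406103 was 3.83-fold higher (2.89 to 5.17). A 4-exon gene on scaffold 1 (14273738 to 14275209), the most abundant of the 15 top-ranked higher genes, was 2.81-fold higher (2.44 to 3.24), at 45.6 and 128 CPM.

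The genes lower in the symbiotic library reached higher levels of expression. Model cHydvir-v1B3C1_g27169 (scaffold 6, positions 7329019 to 7330005, plus strand, 1 exon, 987 nt) ranked first. It had 1140 aposymbiotic and 145 symbiotic counts, a log2 ratio of -3.26 (95% counting interval -3.53 to -3.02). Its upstream neighbour on the same strand (7317527 to 7328623, 3 exons, 11097 nt) lies 395 bp away and had 1296 aposymbiotic and 227 symbiotic CPM, a log2 ratio of -2.51 (-2.59 to -2.43). Model cHydvir-v1B3C1_g22836 (scaffold 4, positions 14461854 to 14462905, minus strand, 3 exons, 282 nt) ranked second, with 138 and 14 counts and a log2 ratio of -3.54 (-4.50 to -2.80). A single-exon model on scaffold 5 (18033335 to 18033844) had 274 and 39 counts and a log2 ratio of -3.09. A 9-exon gene on scaffold 9 (745585 to 782262) had 867 and 253 counts and a log2 ratio of -2.07.

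A few abundant transcripts, 10 of the 1992 with a mean CPM of at least 100, were at least 2-fold lower in the symbiotic library. The 9-exon gene on scaffold 12 (11254353 to 11257979, minus strand, 1938 nt) had 24239 aposymbiotic and 9442 symbiotic counts, a log2 ratio of -1.65 (-1.69 to -1.62). A 4-exon gene on scaffold 5 (18713831 to 18717765) had 765 and 277 CPM, a log2 ratio of -1.46. Neighbouring models on scaffold 5 at 15458483 to 15460658 and 15460735 to 15477961, both on the minus strand and 76 bp apart, had log2 ratios of -1.24 and -1.56. A 2-exon gene on scaffold 8 (17411827 to 17415633) had 430 and 152 CPM. The 15 top-ranked lower genes lay on 10 scaffolds, and none of them overlaps another model. They spanned mean levels from 5.56 to 2860 CPM, whereas the 15 top-ranked higher genes spanned 5.04 to 86.9 CPM.

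Among the 10 most abundant transcripts, log2 ratios ran from -0.079 to 0.35. The largest, a 63-exon gene on scaffold 12 (11363756 to 11377184), took 1.06% of the aposymbiotic total (95% Clopper-Pearson interval 1.06 to 1.07) and 1.17% of the symbiotic total (1.16 to 1.18). A 2-exon gene on scaffold 7 (1820110 to 1821381) took 0.897% and 0.880%, a log2 ratio of 0.0012 (-0.016 to 0.018). The 4 genes of at least 10000 nt among the 10 largest were all higher in the symbiotic library, by less than 2-fold. These were the 29-exon gene of 16419 nt on scaffold 13 (1663446 to 1684324) at a log2 ratio of 0.35 (0.33 to 0.37) and the 14-exon gene of 24900 nt on scaffold 10 (16648140 to 16680312) at 0.32 (0.31 to 0.34). The 33-exon gene of 12489 nt on scaffold 1 (28211651 to 28228364) stood at 0.13 (0.11 to 0.15). A 104-exon gene of 20592 nt on scaffold 3 (2257256 to 2307066) stood at 0.15 (0.13 to 0.17). The robust standard deviation of the log2 ratio was 0.154 among genes of 3000 or more counts, which the counting intervals do not cover. The ratios of these last 2 genes lay within it.

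Over all tested genes, the ratio moved with coding length. The median log2 ratio was -0.029 (95% interval -0.048 to -0.012) in the quintile of shortest genes, up to 597 nt, and 0.052 (0.043 to 0.062) in the quintile of longest genes, from 2202 nt. The difference of 0.081 compares with -0.015 to 0.011 over 100 draws of counting error alone. Genes within a quintile varied far more than the medians, from -1.01 to 0.81 (5th to 95th percentile) among the shortest and from -0.41 to 0.51 among the longest. Spearman's rho between coding length and log2 ratio was 0.0892 across genes, and it was 0.0430 for exon number and 0.0467 for mean CPM. Of the 119 genes of at least 10000 nt, 66.4% lay above 0, against 51.9% of all tested genes. Genes with 5 or more exons had a median of 0.023 (0.018 to 0.029), and single-exon genes one of -0.0026 (-0.023 to 0.012). Longer genes were also more highly expressed, with a median of 3.93 CPM in the shortest and 63.6 CPM in the longest quintile. By quintile of mean CPM, the median log2 ratio was -0.028 (-0.065 to 0.0070) in the lowest and 0.027 (0.021 to 0.034) in the highest. Length was not compared at matched expression.

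**Figure D3:**
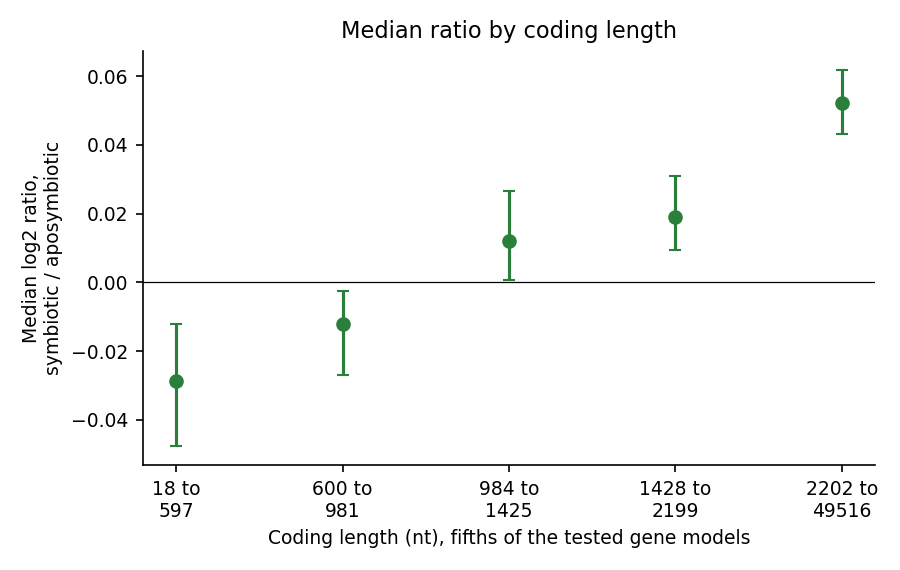
Median log2 ratio of symbiotic over aposymbiotic CPM by quintile of coding length in nt, with exact 95% order-statistic intervals over genes. The medians run from -0.029 in the shortest to 0.052 in the longest quintile, each quintile holding between 3220 and 3252 genes.

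No count in either library was recorded for 9829 of the 34573 models, 28.4%. Of these models 84.8% had a single exon, against 41.0% of models with counts. Many single-exon models share an exact coding length: 23 lengths were each shared by at least 100 models, 4775 models in all, and 69.9% of those had no count. Among other single-exon models 36.5% had none, and among models with several exons 9.30%. The most frequent length, 354 nt, occurred 512 times on 57 scaffolds, and 90.0% of those models had no count. Models were grouped by length alone, without their sequence. Reads with several alignments were not admitted to the counts, so the absence of counts does not show that a model is not transcribed. On scaffold 5, the 5 lengths of 312, 390, 405, 411 and 576 nt recurred together in a repeat. Their median spacings there were between 7600 and 7745 bp, and 573 of the 600 models of these lengths on scaffold 5 had no count. Summed, the 600 models had 106 aposymbiotic and 132 symbiotic counts, a log2 ratio of 0.02 (-0.36 to 0.41). This sum holds only reads with a single alignment and comes from the few models with counts, some of which need not lie in the repeat. It therefore leaves open whether transcript levels of the repeat differed.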

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

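Leaving out scaffold 60 was chosen after seeing the data; all other alternatives were fixed before the data were examined. Under the 4 other scalings, the 4 counts of genes stayed within 1.5 times those reported. Other count filters, the interval and the prior count moved some of them further. With a mean CPM of at least 10, 13 genes were at least 2-fold higher and 51 lower. By the 4-fold rule, 5 were higher and 6 lower. The 2-fold counts were 0.137% and 0.538% of the genes that entered, against 0.947% and 1.42% at a mean CPM of at least 1. The calls thus fell by more than the number of genes did. With every gene of at least 1 count, 101 genes were at least 4-fold higher and 130 lower. With no interval required, 320 were at least 2-fold higher and 425 lower; with the stricter interval, 44 and 89, and 25 at least 4-fold lower. A prior count of 5 left 20 genes at least 4-fold higher and 15 lower, because it shrinks low counts. Without scaffold 60, 142 genes were at least 2-fold and 34 at least 4-fold higher, and 4 models were seen in the symbiotic library alone. At a minimum of 50 counts, 7 models were seen in the symbiotic and 0 in the aposymbiotic library alone; at 10 counts, 3 in the aposymbiotic alone. The median log2 ratio of the shortest quintile was -0.056 with total counts alone and -0.049 with totals without the 100 largest genes. That of the longest quintile was 0.025 and 0.032, and 0.039 with the upper quartile. The difference between the quintiles stayed at 0.081 under each scaling, since a scaling shifts both alike. Of the 20 alternative ratios of the 4 genes given by identifier, 2 left their counting interval, both under the prior count of 5 (5.51 and 5.48 for the scaffold 60 models), and none changed sign. Gene list medians were not run under any alternative, because no list could be formed. Below a mean CPM of 10, depth limits what single genes show.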

Other observations

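Some genes lower in the symbiotic library lay beside each other. Outside scaffold 60, 22 pairs of neighbouring tested genes met the 2-fold rule in the same direction, 20 of them lower, where 1000 shuffles of the calls along the scaffolds gave 4.47 on average and at most 12. The lower pairs held 36 of the 229 lower genes, 15.7%, and in 2 of the 22 pairs both genes had a mean CPM of at least 10. Most pairs thus held a gene of low expression, where counting error also gives calls, and a run of 3 genes entered as 2 pairs. The excess over the shuffles therefore does not by itself show joint regulation. Of the 22 pairs, 63.6% were on 1 strand, against 57.0% of all neighbouring pairs. Besides the pairs on scaffolds 5 and 6 given above, 3 models in a row on scaffold 6 were lower (1165192 to 1165518, 1166691 to 1168299 and 1168356 to 1169727, log2 ratios of -1.19, -1.18 and -1.03). A pair on scaffold 3 (18875390 to 18875954 and 18913851 to 18914249) had log2 ratios of -2.78 and -2.66.

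In the weighing that follows, the tests of counting error, of mitochondrial coding lengths and of the histone repeat were chosen after the results were seen. The others were written before their own outcome was seen, but after the patterns they address had been found. Scaffold 60 had counts in the symbiotic library alone, and counting error is excluded as the cause, since the symbiotic counts predict 824 aposymbiotic counts where there were 0. A candidate explanation is that the scaffold is sequence of the alga, such as its mitochondrial genome, assembled with the host. Its 15 coding lengths filled 10 of 13 length ranges of mitochondrial genes, where the median run of 15 consecutive models elsewhere filled 5. The ranges came from general knowledge but were set after these lengths had been seen, so the contrast is no independent support. Of 33679 runs, 15 filled as many, and lengths alone leave an origin from the alga open. A host segment that is silent in, or missing from, aposymbiotic polyps cannot be told apart from it: coding sequence covers 25.8% of the span of scaffold 60, and 1170 of 32488 runs on the 16 largest scaffolds were as dense with as many single-exon models. The sequence of the scaffold was not used here and would decide.

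The ratio rose slightly with coding length. Counting error is excluded, as the difference of 0.081 between the longest and the shortest quintile lies above the 0.011 it reached in 100 draws. The difference was 0.080 without the 100 largest genes, which decides nothing about them, because they make up only 0.277% of the shortest and 1.08% of the longest quintile and can hardly move a median. A difference in RNA fragmentation or library preparation may give such a trend, and the trend held inside each class of exon number, by at least 0.061. With 1 library per condition this and an effect of the alga on long transcripts cannot be told apart. Longer genes were also more highly expressed, and a trend with expression was not separated from the trend with length.

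The repeat of 5 coding lengths on scaffold 5 may be a histone gene cluster, a hypothesis that rests on lengths alone: 411 nt and 312 nt encode 136 and 103 residues, the usual sizes of histones H3 and H4. Of the 174 models of 312 nt in the annotation, 100 had all 4 other lengths within 8 kb (at most 6 in 100 shuffles of the lengths), but the lengths were picked because they recur together and any tandem repeat would show this, so it does not bear on what the genes are. Of 716 models with another of the same length within 20 kb, 97.8% had no count, against 48.8% of 521 models without one. Only 2 of those 521 had all 5 lengths within 8 kb, so the rest need not be copies of the repeat, and the contrast decides nothing about reads that fit several copies being left uncounted, or about copies that are not transcribed. The summed counts of the 600 models of these lengths on scaffold 5 did not differ detectably between the libraries. Some of the models with counts need not lie in the repeat, so the sum leaves open whether transcript levels of the repeat differed. None of these tests decided on a biological explanation.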
